A study of Mus musculus with 8 samples.

How the data were processed

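Gene expression was measured in MC3T3-E1 cells, a mouse osteoblast line derived from skull bone, grown together with tumour cells that overexpressed the Notch ligand Jagged1 or carried the empty vector. The co-cultures received the solvent DMSO or MRK-003, an inhibitor of gamma-secretase, the protease that releases the active part of Notch receptors. The 4 groups (vector DMSO, Jagged1 DMSO, vector MRK-003 and Jagged1 MRK-003) had 2 biological replicates each, on 8 arrays. Per the labels' protocols, 175 ng of total RNA was amplified and labelled, with each co-culture in Cy3 and a commercial mouse reference RNA in Cy5 on every array, so no dyes were swapped and dye bias stays in each level but not in differences between groups. The tumour line, its species, and how osteoblasts were separated from tumour cells before RNA extraction are not given in the sources used here.

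Per the file headers, the authors scanned Agilent mouse arrays and extracted spot values with Agilent Feature Extraction 9.5.3.1, with probe coordinates on build mm7. The deposited intensity values used here were the mean signal and the median local background of each spot in both channels, with no normalization, and the scanner software's processed signals, which per the file headers were background-subtracted and dye-normalized. The deposited log10 ratio of Cy5 over Cy3 was also made by that software, and its sign was turned so that every value here is sample over reference. The deposited 0 or 1 flags of each spot gave outliers, saturation and whether it was well above background. The authors' deposited value table, on a log2 scale, matched the log2 ratio of the scanner software's processed signals, sample over reference, plus 1 constant per array (100% of probes within 0.02), so its scale, centring and direction were known. Its medians per column were 0.11, 0.21, 0.15, 0.17, 0.13, 0.16, 0.16 and 0.15 in the order vector DMSO, Jagged1 DMSO, vector MRK-003 and Jagged1 MRK-003, replicates 1 and 2 of each.

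Each array held 45018 spots, of which 1639 were controls and the others covered 41174 probes. The background was corrected by normexp with an offset of 50 in each channel, and the ratio was normalized by loess within each array with control spots given no weight. Spots with an outlier mark were left out, which removed 227 probes. Spots of 1 probe were averaged, and a probe was kept where Cy3 was well above background on both arrays of at least 1 group, which removed 7887 dim probes and left 33060. Names came from a table of RefSeq genes for 22951 probes matched by accession without versions, and 18223 kept the name in the files. Each of 23441 genes was represented by its brightest probe in Cy3, and 6957 genes had more than 1 probe.

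limma 3.58.1 in R 4.3.3 fitted the 4 group means to all 8 arrays, with Benjamini-Hochberg adjusted p under 0.05 within each of 6 comparisons: Jagged1 against vector in DMSO and in MRK-003, MRK-003 against DMSO with each kind of tumour cell, the interaction (the Jagged1 effect in DMSO minus that in MRK-003) and the average MRK-003 effect. The groups share 1 estimate of the spread, and 2 arrays per group limit the precision. Gene lists were tested with camera in limma at a preset correlation of 0.01, with the correlation estimated from the data and with fry as alternatives, and were adjusted over the lists within each comparison. Errors beside log2 changes are standard errors from limma, and those beside group levels are standard deviations over 2 arrays. Where a probe was not well above background on every array of a group, the fold is a lower bound, computed from each channel after loess and Aquantile against the lowest signal among probes well above background, and it is open to dye bias. The grouping, the comparisons, the lists, the naming rule and most alternatives were fixed before the data were examined.

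The 21 lists were canonical Notch targets, Notch pathway machinery, osteoblast differentiation and bone matrix, osteoblast factors that regulate osteoclasts, cytokines and chemokines, interferon-stimulated genes, cell cycle and DNA replication, contractile genes, matrix proteases and their inhibitors, cholesterol synthesis, TGF-beta and BMP response, Wnt targets, unfolded protein and integrated stress response, hypoxia and glycolysis, immediate early genes, and markers of 6 other cell types (epithelial, macrophage, osteoclast, adipocyte, chondrocyte and endothelial). Named genes were symbols only. In the comparisons of Jagged1 in DMSO, MRK-003 with Jagged1 and the interaction they were the 8 largest rises and 8 largest falls that passed with no overlap between the arrays compared (no overlap rule for the interaction), and in the others the 5 and 5. A direction with fewer was filled up to 5 with the smallest p values, named as not passing. Notch targets, Jag1, Il6 and up to 4 members with the smallest p of each called list were added, and 2 of these members are not reported here.

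Replicate 1 of every group lay on 1 slide and replicate 2 on the other, and each group had the same position on both slides, so position and group cannot be told apart. The replicate number is therefore also the slide. Arrays of the same number deviated together from their group means in all 6 pairs of groups, with correlations across genes from 0.39 to 0.75. With the limited background described below they were 0.37 to 0.85. The pair at 0.75, Jagged1 DMSO with Jagged1 MRK-003, was then at 0.37. The numbers were therefore taken to pair the arrays, and the fit with the replicate as a block is given where it changes a call. The planned main fit does not use this pairing, so slide differences stay in its spread. For Jagged1 in DMSO it called 4 genes, against 107 with the block. The replicates' log2 ratios correlated across genes at 0.92, 0.91, 0.90 and 0.83 in the 4 groups in the order above, and none held identical values.

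A few spots with extreme local background, up to a Cy3 brightness of 32904 where the array medians were 27 to 30.5, distorted the normexp fit on both Jagged1 DMSO arrays and on replicate 2 of Jagged1 MRK-003. On these arrays the Cy3 negative controls stayed at 91.2, 326 and 385 after correction, against 6.32 to 17.6 on the other 5. The log2 ratios of those 3 arrays had standard deviations of 0.72, 0.55 and 0.58, against 0.75 to 0.81 on the others. An alternative chosen after seeing the data replaced every local background over 2 times the array's median by that median before normexp; it is called the limited background here. It left the negative controls at 6.32 to 8.28 and the standard deviations at 0.77 to 0.81. Among the named genes it gave 56 further calls and ended none. Its values stand beside the planned ones where they end or add a call of a list, and for genes mostly as counts. All 3 distorted arrays were of Jagged1 co-cultures, so planned gene values in comparisons with these arrays can carry the distortion. Epcam, for example, was at -3.82 with vector and -2.59 with Jagged1 cells in DMSO as planned. With the limited background Epcam was at -3.88 and -3.85, whereas Krt8 moved less.

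The test was tried on simulated data for the Jagged1 comparison in DMSO, with 200 of 23441 genes changed. A log2 change of 1 was recovered for 41.5% of them with 0 false calls, and for 90.0% with 10 false calls when the replicate was a block. A log2 change of 2 was recovered for 88.0% with 0 false calls, and for 99.5% with 14 false calls with the block. The simulated arrays held the fitted slide effect and independent normal noise with the spread of the block fit, which favours the block. They did not imitate the distorted Jagged1 arrays or correlation between genes, so these rates may not hold for the real data. Alternatives covered the offset, no background subtraction, the scanner software's log ratio, median centring, Cy3 alone, the authors' table, filters, all probes, the block, the arrays in the fit, the variance model, array weights and each array left out. No genome of build mm7 was used here.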

Results

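The series measured messenger RNA in MC3T3-E1 mouse osteoblasts grown with vector or Jagged1-overexpressing tumour cells, under DMSO or the gamma-secretase inhibitor MRK-003. It asked which osteoblast genes respond to Jagged1 from tumour cells and which of these responses need Notch signalling. There were 4 groups of 2 biological replicates, 1 array each. The median Cy3 signal was 183 and 76.5 for vector DMSO, 184 and 94.3 for Jagged1 DMSO, 204 and 99.3 for vector MRK-003 and 165 and 117 for Jagged1 MRK-003 (replicates 1 and 2). Cy3 was well above background for 86.0% to 89.4% of spots on the replicate 1 arrays and 71.4% to 78.6% on the replicate 2 arrays.

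With Jagged1 tumour cells in DMSO, Dtx4, a Deltex-family ubiquitin ligase linked to Notch signalling, rose by 1.70 ± 0.10 on the log2 scale (SE, n = 2 per group, adjusted p = 0.0243). Dbndd2, a dysbindin domain protein, rose by 1.72 ± 0.08, a 3.29-fold change (adjusted p = 0.00831). Slc16a1, a transporter of lactate and pyruvate, fell by 1.16 ± 0.08 (adjusted p = 0.0448). Hey1, a transcriptional repressor induced by Notch, was at -0.58 ± 0.05 over the reference with vector cells and at 2.99 ± 0.29 with Jagged1 cells (SD, n = 2). Hey1's difference of 3.57 ± 0.43 did not pass (adjusted p = 0.129), but did with the replicate as a block (adjusted p = 0.0415) and with the limited background (3.76 ± 0.18, adjusted p = 0.0025). The same held for Jag1 itself, at 1.07 ± 0.14 (adjusted p = 0.131, with the block 0.0428, and with the limited background 1.26 and 0.0179). On build mm7 the probes were those of Hey1 on chromosome 3 at 8669867 to 8669926, Dtx4 on chromosome 19 at 12146568 to 12146627, Dbndd2 on chromosome 2 at 164231113 to 164231172, Slc16a1 on chromosome 3 at 104451002 to 104451061 and Jag1 on chromosome 2 at 136822550 to 136822609.

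By limma, 4 of 23441 genes passed in this comparison, 2 higher and 2 lower with Jagged1, and 1920 had an unadjusted p under 0.05. The remaining one, named after its values were seen, was the transcript ENSMUST00000074660, which fell by 3.09 (adjusted p = 0.00831). The arrays of the 2 groups did not overlap for these genes, as happens by chance for 33.3% of genes with 2 against 2. With the replicate as a block 107 genes passed (41 higher, 66 lower), with the limited background 41 (32 higher, 9 lower), and with both 898 (327 higher, 571 lower); all 4 were among each of these sets. No gene passed when either vector DMSO array, replicate 1 of Jagged1 DMSO or either vector MRK-003 array was left out, and 1 passed without replicate 2 of Jagged1 DMSO. The probes of Dbndd2 (1.72 and 1.71) and of Dtx4 (1.70, 1.34 and 1.12) shared their direction, whereas 1 of the 3 Slc16a1 probes was at -0.12 and the dimmer Jag1 probe, well above background on 5 arrays, at 0.06.

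Further genes with the smallest p values did not pass. Those with positive differences were Eif2b2, a subunit of a translation initiation factor (1.20 ± 0.10, adjusted p = 0.0679), the septin Septin5 (0.98) and the kinase Prkcd (0.92, adjusted p = 0.0679). Those with negative differences were Trp63, a transcription factor of epithelial stem cells (-2.26 ± 0.23, adjusted p = 0.111), the small GTPase Rab30 (-1.82), the calcium channel Cacna1g (-1.05) and the scavenger receptor Colec12 (-1.03). The other Trp63 probes were at -0.09 (well above background on 8 arrays) and -0.41 (on 4). All 7 passed with the replicate as a block, at adjusted p from 0.0252 for Prkcd to 0.0407 for Trp63, and Eif2b2, Septin5 and Prkcd also with the limited background.

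Among 16 measured canonical Notch targets, 13 were higher with Jagged1, and the mean difference was 0.53 ± 0.91 (SD over genes). The list passed camera (adjusted p = 1.13e-04), but not with an estimated correlation (adjusted p = 0.202). Its mean was 0.54 on slide 1 and 0.53 on slide 2. No member passed over all genes and 2 did adjusted over the list alone; with the limited background 3 and 5 did, among them the receptor Notch3 (1.66 ± 0.31, adjusted p = 0.246; limited 1.65, adjusted p = 0.0115) and the feedback inhibitor Nrarp (0.42, adjusted p = 0.508; limited 0.97, adjusted p = 0.0288). Hes1, a repressor and Notch target, was at 0.34 ± 0.22 (adjusted p = 0.677), Notch1 at 0.44, Efnb2 at 0.60, Hes6 at 0.26, Hes5 at 0.15, Hes2 at 0.13, Lfng at 0.31, Dll4 at 0.07, Hes3 at -0.03, Nrip2 at -0.06 and Hes7 at -0.08. The 2 probes of Heyl were at 0.19 and -0.08. Dtx1 was not well above background with vector cells and, with the planned background, at least 1.26-fold higher with Jagged1 (adjusted p = 0.627). That bound can carry the distortion of both Jagged1 DMSO arrays, so it is not a firm minimum.

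Of the 30 cell cycle genes, 29 were lower with Jagged1 in DMSO, with a mean of -0.43 ± 0.17 (SD over genes, camera adjusted p = 6.64e-15, adjusted p = 0.202 with an estimated correlation). The replication genes Pcna (-0.70), Mcm4 (-0.69) and Cdc6 (-0.54) did not pass over all genes, and 11 members were lower adjusted over the list alone. The list's mean was -0.51 on slide 1 and -0.36 on slide 2. Of 24 cholesterol synthesis genes, 22 were lower (mean -0.32, adjusted p = 1.94e-06, and 0.346 with an estimated correlation). Leaving out 1 array gave -0.50 to -0.13. Among them were Idi1 (-0.88), Sc5d (-0.82), Hmgcs1 (-0.71) and Msmo1 (-0.67), of which none passed over all genes and 5 members did adjusted over the list alone.

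Factors by which osteoblasts regulate osteoclasts had a mean difference of 0.41 over 18 genes, 13 of them positive (camera adjusted p = 5.32e-04, and 0.202 with an estimated correlation). The matricellular growth factor Ccn2 was at 2.63 ± 0.43 (adjusted p = 0.217), Tgfb2 at 1.16, Tgfb1 at 0.99 ± 0.13 (adjusted p = 0.131) and the chemokine Cxcl12 at 0.62; no member passed over all genes (Tgfb1 did with the limited background, adjusted p = 0.0288) and 4 did adjusted over the list alone. Il6, a cytokine that promotes bone resorption, was at 1.12 ± 0.42 (adjusted p = 0.59) and passed with the limited background and the block together (1.73, adjusted p = 0.0268). The 22 cytokines had a mean of 0.48, 18 of them positive (adjusted p = 1.03e-04, and 0.202 with an estimated correlation), with Ccl9 at 1.03, Cx3cl1 at -0.42 and Il11 at 0.33; none passed over all genes and 2 did adjusted over the list alone. With the limited background the cytokine mean was 0.17 (adjusted p = 0.0257, and 0.229 with an estimated correlation). Leaving out 1 array gave 0.30 to 0.67 with the planned background. The 27 matrix proteases and inhibitors had a mean of 0.32 (adjusted p = 0.00488, and 0.202 with an estimated correlation), with Loxl1, which crosslinks elastin, at 1.31, Mmp11 at 1.06 and Adamts2 at 0.66; none passed over all genes and 4 did adjusted over the list alone.

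Of the 6 lists of markers of other cell types, 3 passed camera in the same comparison and none did with an estimated correlation. All 18 epithelial markers were higher with Jagged1 (mean 0.53, camera adjusted p = 8.17e-05, and 0.346 with an estimated correlation), among them Krt7 (0.81), Lamb3 (0.70), Krt14 (0.52) and Krt5 (0.16), and 11 of 14 macrophage markers were higher (mean 0.60, adjusted p = 0.00125, and 0.438 with an estimated correlation), among them Adgre1 (1.06), Csf1r (0.80), Coro1a (0.71) and Fcer1g (0.51). With the limited background these means were 0.11 (adjusted p = 0.0582) and 0.04 (adjusted p = 0.667), and the macrophage mean was -0.01 in Cy3 alone. Without replicate 1 or 2 of Jagged1 DMSO the macrophage mean was 0.92 or 0.27 (adjusted p = 0.118 for the latter). The epithelial mean was 0.76 or 0.30. The 11 osteoclast markers had a mean of 0.21 (adjusted p = 0.0402, with an estimated correlation 0.234, with the block 0.0793), led by the integrin subunit Itgb3 (1.14 ± 0.13, adjusted p = 0.128), with Acp5 at 0.48, Oscar at 0.23 and Ocstamp at 0.20. With 1 array left out the osteoclast marker mean ran from 0.18 to 0.25, and the call was not kept each time. No marker of these 3 lists passed over all genes; adjusted over the list alone 1 osteoclast marker did. Of the list members named for this comparison, Loxl1 (adjusted p = 0.017), Itgb3 (0.0252, and 0.0323 with the limited background), Ccl9 (0.0369), Tgfb1 (0.0415) and Mcm4 (0.0462) passed with the replicate as a block. Means that did not pass were 0.31 for adipocyte (adjusted p = 0.211), -0.27 for chondrocyte (0.05004) and 0.16 for endothelial markers (0.317).

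The other lists did not pass in this comparison. Notch pathway machinery had a mean of 0.17 (adjusted p = 0.17, and with the limited background 0.0302, or 0.229 with an estimated correlation), osteoblast and bone matrix genes -0.19 (adjusted p = 0.129), contractile genes 0.13 (0.361), TGF-beta and BMP response genes 0.20 (0.317), Wnt targets -0.22 (0.268) and stress response genes 0.03 (0.547, with a mean of -0.06 in the limited background). Hypoxia and glycolysis genes had a mean of 0.17 (0.317, with a mean of -0.03 in the limited background) and immediate early genes -0.08 (0.317). Interferon-stimulated genes were at 0.14 (0.361), and at -0.16 with the limited background (adjusted p = 0.043, and 0.47 with an estimated correlation). No member of these 9 lists or of the adipocyte, chondrocyte and endothelial lists passed over all genes; adjusted over the list alone, 2 machinery, 1 osteoblast, 3 TGF-beta and BMP, 4 Wnt, 1 hypoxia, 2 chondrocyte and 1 endothelial gene did. Over all genes, 2 machinery, 1 osteoblast and 1 Wnt gene passed with the limited background.

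**Figure D1:**
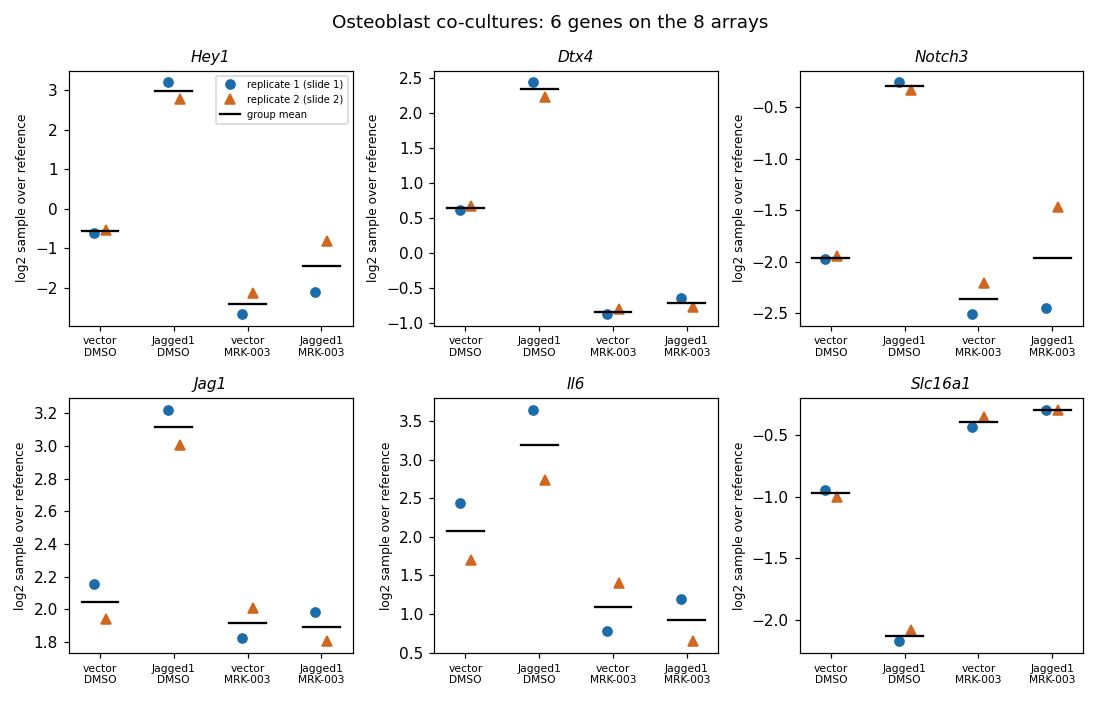
Log2 ratio of sample over reference (vertical axes) of 6 genes in the 4 groups, with circles for replicate 1, triangles for replicate 2 and lines for group means. Hey1 lay at 2.99 on average with Jagged1 cells in DMSO and at -1.46 with Jagged1 cells in MRK-003, whereas Slc16a1 lay at -2.13 and -0.30.

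With MRK-003 present, the levels with Jagged1 and with vector tumour cells differed in no gene that passed. Hey1 differed by 0.95 ± 0.43, Notch3 by 0.40, Hes1 by 0.05, Jag1 by -0.02 ± 0.14 and Il6 by -0.17 ± 0.42 (SE, n = 2 per group), with adjusted p values of 1. The genes with the smallest p values were Aig1 (0.38), the Wnt-regulated factor Lef1 (0.45), Cpeb2 (0.44), Gnb4 (0.50) and Mbd4 (0.27) among positive differences, and Hhip (-0.35), the Wnt inhibitor Dkk2 (-0.73), Fggy (-0.47), Zfhx4 (-0.55) and Adamts6 (-0.38) among negative ones. Other probes were at 0.23 for Aig1, 0.75 for Lef1, -0.03 and -0.08 for Cpeb2 and 0.05 for Gnb4. limma called 0 of 23441 genes with 156 at an unadjusted p under 0.05. It also called 0 with the block (555 unadjusted), the limited background (55 unadjusted) and both (251 unadjusted). All of these unadjusted counts were below the share of 0.05 of the genes that chance alone gives, so the test was conservative here. The 0 calls therefore do not show that no gene differed.

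The Notch target list had a mean of 0.13 between Jagged1 and vector cells in MRK-003 (camera adjusted p = 0.058) and the cell cycle list 0.01 (0.666). With 1 array left out the Notch target mean ran from 0.07 to 0.18. The lists that passed were cytokines (mean 0.27, adjusted p = 0.00397), matrix proteases (0.14, adjusted p = 0.0126, with the block 0.0573), stress response genes (0.10, adjusted p = 0.0124), epithelial markers (0.30, adjusted p = 0.00101) and macrophage markers (0.39, adjusted p = 1.64e-04), and no member passed over all genes or adjusted over the list alone. Members with the smallest p were Cxcl12 (0.25), Plau (0.66), Hyou1 (0.25), Lamb3 (0.51) and Csf1r (0.57). With an estimated correlation the adjusted p values were 0.359, 0.359, 0.549, 0.549 and 0.549, and with the limited background 0.921, 0.404, 0.404, 0.764 and 0.921, with the epithelial and macrophage means at -0.04 and -0.01. With median centring in place of loess, the means were -0.16 for matrix proteases and -0.29 for stress response genes. The latter then passed in the opposite direction (camera adjusted p = 0.0096). The epithelial mean was -0.05 on slide 1 and 0.64 on slide 2, and the macrophage mean -0.05 and 0.84. Without replicate 2 of Jagged1 MRK-003 the cytokine mean was 0.010 (adjusted p = 0.754) and the stress response mean 0.021 (0.632), and without replicate 1 they were 0.53 and 0.19. With the block, interferon-stimulated genes (mean 0.17, adjusted p = 0.0316) and chondrocyte markers (-0.13, adjusted p = 0.0445) passed too, where without it both were at 0.058, and at 0.652 and 0.56 with an estimated correlation. Their means with the limited background were 0.03 and 0.025, and neither passed. Osteoclast (0.05, adjusted p = 0.666), adipocyte (0.20, adjusted p = 0.058) and endothelial markers (0.07, adjusted p = 0.567) did not pass. No list that passed in any comparison had a mean, a median and a camera direction of different signs, whereas the osteoclast markers here had a median of -0.00477.

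In co-cultures with Jagged1 tumour cells, MRK-003 lowered Hey1, which fell by 4.44 ± 0.43 (SE, n = 2 per group, adjusted p = 0.0324). Dtx4 fell by 3.05 ± 0.10, an 8.3-fold change (adjusted p = 0.00175), Dbndd2 fell by 2.21 ± 0.08, and the cell adhesion molecule Cdh15 fell by 3.09 ± 0.28. Further falls were in the RNA-editing enzyme Adarb1 (-2.50), the growth factor binding protein Igfbp5 (-2.45), the pro-apoptotic gene Bmf (-2.33) and Eif2b2 (-2.01). Other probes well above background on all arrays were at -1.45 for Adarb1, -0.16 for Igfbp5 and -0.08 for Bmf. The largest rises were in Ch25h, an enzyme that makes an oxysterol from cholesterol (3.63 ± 0.39, adjusted p = 0.0405), Thsd4 (2.74), the Wnt ligand Wnt10a (2.48), Trp63 (2.45 ± 0.23), the calcium-binding protein S100b (2.14), Smim3 (1.86), Slc16a1 (1.83 ± 0.08, adjusted p = 0.00301) and the transcriptional coactivator Eya1 (1.77). Other probes were at -0.07 and 0.31 for Trp63, 1.66 and 0.14 for Slc16a1, 1.30 for Thsd4 and 0.80 for Eya1.

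By limma 71 genes passed, 28 higher and 43 lower with MRK-003, and 2014 had an unadjusted p under 0.05. With the block 505 passed (299 higher, 206 lower), with the limited background 481 (230 higher, 251 lower) and with both 2245 (1345 higher, 900 lower), and these sets held 71, 70 and 71 of the 71. Leaving out 1 array left 4 calls (without replicate 1 of Jagged1 DMSO), 6 (without either vector DMSO array or replicate 1 of Jagged1 MRK-003), 11 (without replicate 2 of Jagged1 DMSO) or 13 (without either vector MRK-003 array or replicate 2 of Jagged1 MRK-003), and the genes named here were not all among them. The naming rule admitted only genes with no overlap between the arrays compared. That forced the same direction on both slides for each gene named above, so this agreement is no support. Hey1 was at -5.30 and -3.59 on the 2 slides.

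Among the 16 Notch targets, 11 were lower with MRK-003 in Jagged1 co-cultures, with a mean of -0.61 and a median of -0.13 (camera adjusted p = 1.25e-04, and 0.211 with an estimated correlation). Hey1 passed over all genes, and 4 did adjusted over the list alone. Hes1 (-1.65 ± 0.22, adjusted p = 0.0625), Notch3 (-1.67 ± 0.31, adjusted p = 0.125) and Il6 (-2.28 ± 0.42, adjusted p = 0.127), which is not in the list, passed with the block (adjusted p = 0.0217, 0.0424 and 0.0473) and with the limited background (0.0208, 0.00212 and 0.0158). Nrarp was not well above background with MRK-003 and at least 1.26-fold higher in DMSO (adjusted p = 0.594, and 0.0139 with the limited background). The bound is from the planned background and can carry the distortion of the Jagged1 DMSO arrays. Hes6 was at -0.59, Notch1 at -1.09 (adjusted p = 0.483, and 0.0357 with the block) and Heyl at -0.24. In the list of pathway machinery (mean -0.18, adjusted p = 0.0353, and 0.306 with an estimated correlation), Jag1 fell by 1.22 ± 0.14 (adjusted p = 0.0436), while its dimmer probe was at -0.14.

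The cell cycle list was higher with MRK-003 in 28 of 30 genes, with a mean of 0.45 (camera adjusted p = 7.68e-16, and 0.29 with an estimated correlation), including Mcm3 (0.99), Mcm4 (0.78), Cdc6 (0.64) and Rrm1 (0.63). No member passed over all genes (6 did with the limited background) and 13 did adjusted over the list alone, 12 of them higher. Cholesterol synthesis genes were higher in 19 of 24 (mean 0.33, adjusted p = 4.33e-07, and 0.401 with an estimated correlation; 0.10 to 0.57 with 1 array left out), with Sc5d at 0.92, Idi1 at 0.90, Msmo1 at 0.80 and Hmgcs1 at 0.60; none passed over all genes (2 did with the limited background) and 7 did adjusted over the list alone. Among osteoclast regulators (mean -0.40, adjusted p = 0.0435, with an estimated correlation 0.401, with the block 0.175, with the limited background 0.147) Tgfb1 fell by 1.52 ± 0.13 (adjusted p = 0.0286), and Ccn2 was at -2.48 ± 0.43 (adjusted p = 0.111); 6 members passed adjusted over the list alone. Among matrix proteases (mean -0.28, adjusted p = 0.0234, and 0.306 with an estimated correlation) Mmp11 fell by 1.53 (adjusted p = 0.032) and Loxl1 fell by 1.49 (adjusted p = 0.0333), while Timp3, a protease inhibitor, was at 1.42 (adjusted p = 0.0636); 6 members passed adjusted over the list alone.

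A further 6 lists in the same comparison passed with the preset correlation and were lost with an estimated one. Immediate early genes were at a mean of -0.37 (adjusted p = 0.0274, 0.417 estimated, and 0.127 with the limited background), with Ier2 at -1.24, Junb at -1.0, Dusp1 at -0.97 and Zfp36 at -0.88. Interferon-stimulated genes were at 0.18 (0.0323 and 0.456 estimated), with Ifit1 at 0.86, Ifit2 at 0.66 and Bst2 at 0.53. Hypoxia and glycolysis genes were at 0.20 (0.0469 and 0.417 estimated), in which Vegfa was at -1.29 and Bnip3 (1.18), the glucose transporter Slc2a1 (0.96) and Higd1a (0.80, its other probe at -0.07) were positive. Wnt targets were at 0.33 (adjusted p = 0.0469, 0.417 estimated, and 0.0955 with the block), with Tnfrsf19 at 2.60, Nkd2 at 1.64, Ccnd1 at 0.76 and Ccn4 at -1.06. TGF-beta and BMP response genes were at -0.22 (0.0469, 0.401 estimated, and 0.164 with the limited background), with Id4 at 1.31 and Id3 at -0.74, and chondrocyte markers at 0.21 (0.0469, 0.453 estimated, 0.0626 with the block, and 0.164 with the limited background), with Sox9 at 1.15. No member of these 6 lists passed over all genes; adjusted over the list alone 5, 0, 3, 6, 4 and 4 did, and over all genes with the limited background 5, 2, 4, 4, 1 and 0. Leaving out 1 array turned the interferon mean to -0.06 (without replicate 1 of Jagged1 DMSO) or raised it to 0.41 (without replicate 2). The means ran from -0.57 to -0.16 for immediate early genes, -0.33 to -0.10 for TGF-beta and BMP genes and 0.10 to 0.32 for chondrocyte markers. The 6 calls, in the order above, were lost in 2, 2, 5, 7, 4 and 4 of the 8 cases. With the replicate as a block the members Mcm3, Mcm4, Cdc6, Rrm1, Sc5d, Idi1, Msmo1, Timp3, Ier2, Junb, Vegfa, Bnip3, Slc2a1, Higd1a, Ccnd1, Id3 and Tnfrsf19 passed, at adjusted p values from 0.0119 for Tnfrsf19 to 0.0372 for Rrm1. Epithelial markers did not pass (-0.19, adjusted p = 0.0585, with the block 0.0293, with an estimated correlation 0.52), nor did macrophage (-0.16, 0.454), osteoclast (-0.18, 0.13), adipocyte (-0.13, 0.247) and endothelial markers (-0.13, 0.274), though the osteoclast marker Itgb3, named here after its values were seen, fell by 1.68 ± 0.13 (adjusted p = 0.026). The other Itgb3 probe, well above background on 8 arrays, was at -0.41.

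In co-cultures with vector tumour cells, Dtx4 was lower with MRK-003 by the smallest p value, at -1.48 ± 0.10, but did not pass (SE, n = 2 per group, adjusted p = 0.161). Hes1 was at -1.35 ± 0.22, Hey1 at -1.83 ± 0.43, Bmf at -1.24, C1qtnf5 at -0.99, Eif2b2 at -0.91 and Prkcd at -0.59, and on the positive side Smim3 was at 0.82, Slc2a1 at 0.70, Higd1a at 0.62, Slc16a1 at 0.58 and Lurap1l at 0.47. Jag1 was at -0.13 and Il6 at -0.98. limma called 0 genes, with 840 at an unadjusted p under 0.05, below the share of 0.05 of the genes that chance alone gives. It also called 0 with the block (1917 unadjusted) or the limited background (944 unadjusted). With both, 7 genes passed (1 higher, 6 lower), among them Dtx4 (adjusted p = 0.031) and Hey1, Hes1 and C1qtnf5 (adjusted p = 0.0445 each).

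Immediate early genes had a mean of -0.39 with MRK-003 in vector co-cultures (camera adjusted p = 9.71e-04, and 0.761 with an estimated correlation), with Ier2 at -1.12, Dusp1 at -0.99, Zfp36 at -0.91 and Junb at -0.87; 4 passed adjusted over the list alone and none over all genes. Hypoxia and glycolysis genes had a mean of 0.24 (adjusted p = 0.0102, and 0.761 with an estimated correlation), with Hk2 at 0.87 and Vegfa at -0.60, and 2 passed adjusted over the list alone. Interferon-stimulated genes were at 0.15 (adjusted p = 0.0466, and 0.78 with an estimated correlation), with Bst2 at 0.65 and none passing adjusted over the list alone. With 1 array left out the 3 means ran from -0.52 to -0.27, 0.09 to 0.40 and 0.05 to 0.25. The calls were lost in 2, 2 and 3 of the 8 cases. The Notch target mean was -0.21 (adjusted p = 0.153, and 0.026 with the limited background), the Wnt target mean 0.19 (0.115, and 0.0296 with the limited background) and the cell cycle mean 0.01 (0.693). An estimated correlation brought the Notch and Wnt values with the limited background to 0.544 and 0.668. Markers of other cell types did not pass, with means of 0.04 for epithelial, 0.05 for macrophage, -0.02 for osteoclast, -0.02 for adipocyte, 0.06 for chondrocyte and -0.04 for endothelial markers.

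**Figure D2:**
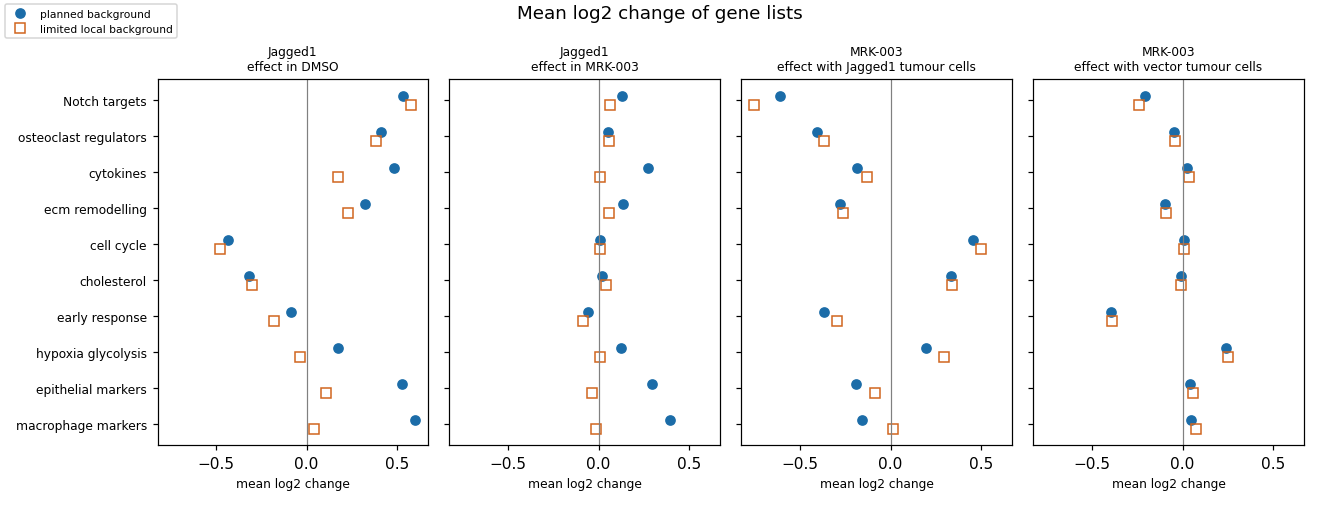
Mean log2 change (horizontal axes) of 10 gene lists in 4 comparisons, with filled circles for the planned background correction and open squares for the limited local background. The Notch target mean was 0.53 with Jagged1 in DMSO and 0.13 in MRK-003, and the epithelial mean of 0.53 in DMSO was 0.11 with the limited background.

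Whether the Jagged1 effect differed between DMSO and MRK-003 was tested by the interaction. Dbndd2 had the smallest p among gene symbols, with a difference of 1.65 ± 0.11 (SE, n = 2 per group, adjusted p = 0.102), followed by Slc16a1 (-1.26 ± 0.11, adjusted p = 0.213) and Dtx4 (1.57 ± 0.14, adjusted p = 0.213). Eif2b2 was at 1.09, Septin5 at 1.02, Prkcd at 0.83, the growth factor Fgf7 at -1.45, the sterol isomerase Ebp at -1.16, Gxylt2 at -1.15 and Colec12 at -1.10. Hey1 was at 2.61 ± 0.61, Jag1 at 1.09 ± 0.19, Notch3 at 1.26 and Il6 at 1.30 ± 0.60. limma called 0 genes, with 508 at an unadjusted p under 0.05, below the share of 0.05 of the genes that chance alone gives. The 0 calls therefore do not show that no gene differed. With the block 0 passed (1487 unadjusted), and with the limited background 4 passed (3 higher, 1 lower). The 4 were Hey1 (3.45, adjusted p = 0.0423), Dbndd2 (1.72, adjusted p = 0.0443) and, named after their values were seen, the adhesion molecule Mcam (2.80, adjusted p = 0.0351) and the Wnt antagonist Nkd2 (-1.89, adjusted p = 0.0443). With the block and the limited background together 91 passed (46 higher, 45 lower).

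By list, the Jagged1 effect was larger in DMSO for Notch targets (mean difference 0.41, camera adjusted p = 0.00113), osteoclast regulators (0.36, adjusted p = 0.00113) and cytokines (0.21, adjusted p = 0.0167), and more negative for cell cycle (-0.44, adjusted p = 7.61e-19) and cholesterol genes (-0.34, adjusted p = 1.03e-08). With an estimated correlation the adjusted p values were 0.219, 0.328, 0.342, 0.219 and 0.342. With 1 array left out the osteoclast regulator mean was 0.20 to 0.51 (not passing in 2 of 8 cases), the cytokine mean -0.05 to 0.47 (not in 5) and the cholesterol mean -0.57 to -0.11. No member passed over all genes, and adjusted over the list alone 0, 1, 1, 0 and 2 did. Examples were Tgfb1 (0.94), Ccl9 (0.98), Mcm4 (-0.68) and Hmgcs1 (-0.75). Markers of other cell types did not pass, with means of 0.23 for epithelial (adjusted p = 0.054, with the block 0.0105, with the limited background 0.0483), 0.21 for macrophage, 0.16 for osteoclast, 0.11 for adipocyte, -0.15 for chondrocyte and 0.09 for endothelial markers. Notch pathway machinery was at 0.14 (adjusted p = 0.135, and 0.0425 with the limited background). An estimated correlation brought both values with the limited background to 0.262.

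Since fewer than 20 genes passed for Jagged1 in DMSO, the 100 genes with the smallest p there were followed, 43 higher and 57 lower. Their median change in the DMSO direction was 1.03 in DMSO, where they were chosen, and 0.10 in MRK-003, whose arrays entered the choice through the shared spread. Genes picked by their DMSO p values tend to have inflated DMSO changes, so the MRK-003 change as a share of the DMSO change is biased low. This share was 9.57%. It ran from 3.72% to 35.0% with 1 array left out, where the 100 genes were chosen again in each fit. With the limited background 41 genes passed and, by the rule, replaced the 100, with a DMSO median of 1.39 and a share of 2.22%. That value therefore differs from 9.57% in its gene set as well as its background. The share was 17.9% when each comparison was fitted to only its own arrays. In MRK-003, 76 of the 100 kept their sign, 0 passed there and 0 passed the interaction by limma, and 99 had an unadjusted interaction p under 0.05, a count largely set by the choice of the genes, since the interaction contains their DMSO effect. In Jagged1 co-cultures 57 of the 100 were called in the opposite direction by MRK-003, a comparison that shares the Jagged1 DMSO arrays. Both genes raised and both genes lowered by Jagged1 were among the oppositely changed genes, an overlap that the shared arrays favour. Across genes these 2 effects correlated at -0.77, and at -0.50 in 100 simulations of unchanged groups on shared arrays, with covariances of -0.0721 and -0.0255, a difference of -0.0466. The simulations were made only for the fit without the block. Computed from different slides, with no shared array, the correlations were -0.55 and -0.58, and genes are not independent replicates.

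Averaged over both kinds of tumour cell, with 4 arrays against 4, MRK-003 lowered Hey1, which fell by 3.14 ± 0.30 (SE, adjusted p = 0.0347). Dtx4 fell by 2.27 ± 0.07 (adjusted p = 0.00172), Bmf fell by 1.79 (another probe was at -0.05), Adarb1 fell by 1.58 and Hes1 fell by 1.5 ± 0.16 (adjusted p = 0.0409). Ch25h rose by 2.57 ± 0.28 (adjusted p = 0.0421), Smim3 by 1.34, Slc16a1 by 1.20, Eya1 by 1.17 and Mvb12b by 0.95. Il6 was at -1.63 ± 0.30 (adjusted p = 0.113, with the block 0.0434, with the limited background 0.0172) and Jag1 at -0.67 (adjusted p = 0.0698, with the block 0.0268, with the limited background 0.0149). By limma 70 genes passed (25 higher, 45 lower), 601 with the block (305 and 296), 447 with the limited background (190 and 257) and 2129 with both (1111 and 1018), and each set held all 70. No gene passed without either vector DMSO array, and 6 to 15 passed without any other array.

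Among lists, Notch targets averaged -0.41 (camera adjusted p = 0.00261), with Hey1 and Hes1 passing over all genes and 4 members adjusted over the list alone. With an estimated correlation none of the 10 lists that passed here did so, with adjusted p values of 0.383 to 0.439. Hypoxia and glycolysis genes averaged 0.22 (adjusted p = 0.0097); Slc2a1 rose by 0.83 and Higd1a by 0.71 (its other probe was at 0.04), and Vegfa, an angiogenic factor, fell by 0.95. Immediate early genes averaged -0.38 (adjusted p = 0.00392), where Ier2 fell by 1.18 and 7 members passed adjusted over the list alone, and matrix proteases -0.19 (adjusted p = 0.0136), where Mmp11 fell by 1.08 and Loxl1 fell by 0.89. Cell cycle genes averaged 0.23 (adjusted p = 3.71e-08), cholesterol genes 0.16 (0.00149), interferon-stimulated genes 0.16 (0.00968) and Wnt targets 0.26 (0.0298), with no member over all genes (4, 1, 2 and 5 with the limited background) and 10, 2, 2 and 6 adjusted over the list alone. Pathway machinery averaged -0.11 (0.046, with the block 0.063) and chondrocyte markers 0.14 (0.0489, with the block 0.0531, with the limited background 0.18). With 1 array left out the means were 0.05 to 0.28 for cholesterol and for interferon-stimulated genes, 0.14 to 0.30 for hypoxia genes and 0.08 to 0.19 for chondrocyte markers. The means of epithelial (-0.08), macrophage (-0.05), osteoclast (-0.10), adipocyte (-0.08) and endothelial markers (-0.08) did not pass, nor did TGF-beta and BMP genes (-0.13, adjusted p = 0.0707, with the block 0.0276, with an estimated correlation 0.427).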

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

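The limited local background was chosen only after the results were seen. The cell cycle pattern was also picked from these results, so the tests of its causes do not stand apart from them. The interaction test was set before.

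The Jagged1 effect differed between DMSO and MRK-003, by camera on the interaction, for 5 gene lists. Of these, the osteoclast regulators and the cytokines share members, among them Il6, Il11 and Cxcl12, so they are not separate findings. Cell cycle genes had a mean interaction of -0.44, with 29 of 30 members negative (adjusted p = 7.61e-19, and 0.219 with an estimated correlation). Canonical Notch targets had a mean of 0.41, with 13 of 16 positive (adjusted p = 0.00113, and 0.219 with an estimated correlation). The osteoclast regulators had a mean of 0.36 with 13 of 18 positive, cytokines and chemokines 0.21 with 17 of 22 positive, and cholesterol synthesis genes -0.34 with 21 of 24 negative, and none of these 3 passed with an estimated correlation (adjusted p = 0.328, 0.342 and 0.342). With 1 array left out, these 3 means ran from 0.20 to 0.51, from -0.05 to 0.47 and from -0.57 to -0.11. The cytokine mean was negative without replicate 1 of Jagged1 MRK-003. The osteoclast regulators did not pass in 2 and the cytokines in 5 of the 8 cases. No search for an array far from the others of its group was run, since each group held 2.

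The cell cycle list was weighed further, since its shift with Jagged1 in DMSO was -0.43 and in MRK-003 0.01. The distorted background fit is argued against as its cause, since 110% of the shift in DMSO was kept with the limited background (camera adjusted p = 1.15e-17, and 0.206 with an estimated correlation). Variation of the reference channel is argued against as well, since 106% of it was kept in Cy3 alone. The shift was not on 1 slide only, since the smaller of the shifts on the 2 slides was 70.3% of the larger. Slower division of osteoblasts that receive a Notch signal could give this pattern and is a hypothesis that was not tested here, and so could the position on the slide, which cannot be told apart from the group, or cell density at harvest.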

How the results depend on the processing

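The limited background at both limits, its combination with the block, and the fits without both Jagged1 arrays of slide 2 were chosen only after the results were seen. The precision is limited by 2 arrays per group and by fewer spots well above background on slide 2 (71.4% to 78.6%). Loess followed by Aquantile leaves log ratios as they are and was not run as a separate fit. The fits without both Jagged1 arrays of slide 2, or without any 1 array, leave a group with 1 array, which is assumed to vary like the others. No setting moved the median of all genes by over 0.1 (the largest shift was -0.09). Unless stated, the cause of a change was not tested.

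Counts follow the order Jagged1 in DMSO, MRK-003 with Jagged1 and average MRK-003 (4, 71 and 70 as planned, and 0 for the other comparisons), and the percentage is the share of the DMSO change that the followed Jagged1 genes kept in MRK-003 (9.57% as planned). That share is biased low, since the genes were picked by their DMSO p values. The genes were chosen again in each setting. All that passed for Jagged1 in DMSO were followed where at least 20 did, and otherwise the 100 with the smallest p. Percentages beside a first count of at least 20 are therefore of other gene sets than the planned 9.57%. Without background subtraction the counts were 43, 488 and 458, with 3 for the interaction and 1.33% for the 43 called genes. The scanner software's log ratio gave 17, 266 and 221 and 2.55%, and the values the authors deposited gave 18, 264 and 209 and 3.03%. Cy3 alone gave 42, 204 and 157, with 3 for the interaction and 2.61% for the 42 called genes. Median centring without loess gave 0, 0 and 0 and 35.3%. An offset of 10 gave 45 for the average, and all probes gave 36. Trend and robust variances gave 2 for Jagged1 in DMSO. Array weights gave 11 for Jagged1 in DMSO and 123 for MRK-003 with Jagged1. Fits to only the arrays compared, which leave 2 residual degrees of freedom, gave 0 for both, and 17.9%. A log2 change of at least 1 as an added condition gave 14.8%.

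With the replicate as a block, which is the same fit as with the slide as a block, the counts were 107, 505 and 601. It gave 56 further calls among the named genes, ended none of them, and ended or gained no list call other than those named in the comparisons above. The limited background gave 41, 481 and 447, with 4 for the interaction and 2.22% for the 41 called genes. A limit of 5 times gave 40, 477 and 443, with 4 and 2.00% for the 40 called genes. With the block added to the limited background the counts were 898, 2245 and 2129, with 91 for the interaction and 7 for MRK-003 with vector cells. The percentage was 1.51% for the 898 called genes. Without both Jagged1 arrays of slide 2 the counts were 0, 0 and 0, and the share 5.30%.

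Leaving out 1 array at a time gave 0 to 6 genes for Jagged1 in DMSO, 0 to 1 for Jagged1 in MRK-003, 4 to 13 for MRK-003 with Jagged1, 0 to 0 for MRK-003 with vector cells, 0 to 1 for the interaction and 0 to 15 for the average. The single gene for Jagged1 in MRK-003 passed without replicate 1 of Jagged1 MRK-003, and that for the interaction without replicate 2 of Jagged1 DMSO. The share kept in MRK-003 was 3.72% to 35.0%, the highest without replicate 1 of Jagged1 MRK-003 and the lowest without replicate 2 of vector MRK-003, with 18.3% without replicate 1 of vector MRK-003 and 4.15% without replicate 2 of Jagged1 DMSO. The Notch target mean was 0.48 to 0.59 for Jagged1 in DMSO, -0.67 to -0.56 for MRK-003 with Jagged1 and 0.35 to 0.46 for the interaction, and passed camera each time (highest adjusted p = 0.0377). Other lists were less stable, and leaving out 1 array weakened 7 to 15 list results each time, the most without replicate 2 of vector MRK-003. The cholesterol mean for Jagged1 in DMSO was -0.133 to -0.503. The interferon mean for MRK-003 with Jagged1 was -0.0566 without replicate 1 of Jagged1 DMSO, and the cytokine mean of the interaction -0.0482 without replicate 1 of Jagged1 MRK-003.

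An estimated correlation ended all 44 list calls. The correlation was estimated only without the block, from 4 residual degrees of freedom that hold the slide differences. A call lost this way therefore does not show that the list was unchanged. For Notch targets, an estimated correlation leaves the means of 0.53, -0.61 and 0.41 as they are, at camera adjusted p values of 0.202, 0.211 and 0.219. With fry the interaction's 0.41 had an adjusted p of 0.194. fry ended 39 of the 44 list calls. It kept those of Notch targets for Jagged1 in DMSO, MRK-003 with Jagged1 and average MRK-003, and of cell cycle genes and osteoclast markers for Jagged1 in DMSO.

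For Jagged1 in MRK-003, the epithelial and macrophage means turned negative without background subtraction (-0.0282 and -0.0112), with the scanner software's log ratio (-0.0499 and -0.0469), with Cy3 alone (-0.0180 and -0.0157), with the authors' value table (-0.0428 and -0.0398) and with the limited background, with or without the block (-0.0351 and -0.0142). They were also negative with a limit of 5 times (-0.0344 and -0.0137) and without both Jagged1 arrays of slide 2 (-0.0613 and -0.0402), and with 1 array left out the epithelial mean ran from -0.0613, without replicate 2 of Jagged1 MRK-003, to 0.65, without replicate 1. With median centring the matrix protease mean was -0.162 and the stress response mean -0.291 in that comparison, the latter passing in the opposite direction (camera adjusted p = 0.0096). The cytokine mean there was -0.0379 with the scanner software's log ratio and -0.0309 with the authors' value table, and with the limited background and the block it was 0.00597 with its camera direction turned. In Cy3 alone the macrophage mean for Jagged1 in DMSO was -0.0106. No named gene turned its direction while called.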

Other observations

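The test of the Jag1 transcript, the limited local background and the genes of the next paragraph were chosen only after the results were seen. The tests of the marker shifts rest on the limited background, so they too came after the results. The splits of the arrays with the planned background were set before.

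A few genes that the naming rule did not choose for a comparison passed there in settings with small counts. Mcam, a cell adhesion molecule, and Nkd2 passed the interaction with the limited background (2.80 and -1.89). Their levels given here are from the planned background, where neither passed. Mcam was at -1.59 over the reference with vector cells in DMSO and at 0.86 with Jagged1 cells, and at -1.81 and -1.33 in MRK-003. The Wnt antagonist Nkd2, a member of the Wnt target list, ran the other way, at 2.15 and 0.12 in DMSO and 2.33 and 1.77 in MRK-003. The interaction of this Nkd2 probe was -1.46 with the planned background, and that of another, well above background on 7 arrays, -0.34. Prag1 fell by 1.81 with MRK-003 in Jagged1 co-cultures (limma adjusted p = 0.0327), and with the limited background and the block it also fell in vector co-cultures, by 0.89 (adjusted p = 0.0459). In the same vector comparison Aldh3a1, an aldehyde dehydrogenase, fell by 1.23 (adjusted p = 0.0445), and the interferon-induced gene Ifi27l2a rose by 0.94 (adjusted p = 0.0459).

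Markers of epithelial cells and macrophages were higher with Jagged1 tumour cells in both treatments with the planned background correction. They passed camera there, but not with an estimated correlation (adjusted p = 0.346 and 0.438 in DMSO, and 0.549 for both in MRK-003). With the limited background the epithelial shift kept 20.5% of its size in DMSO and -11.9% in MRK-003, and the macrophage shift 7.20% and -3.63%, which is consistent with spots of extreme local background as the main source of both shifts. More tumour cell RNA in the Jagged1 co-cultures stays open, since with the limited background the epithelial mean was -0.0351 in MRK-003 but 0.11 in DMSO, too close to the bound set for the test. With the limited background the epithelial transcripts Krt8 (-4.68), Krt18 (-4.92) and Epcam (-3.85) lay far below the reference RNA with Jagged1 cells in DMSO, and with vector cells they were at -4.78, -5.36 and -3.88. With the planned background they were at -4.50, -4.74 and -2.59 with Jagged1 cells and at -4.77, -5.35 and -3.82 with vector cells.

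Jag1 was higher in DMSO with tumour cells that overexpress Jagged1, so the transcript of the tumour cells could have been measured. In MRK-003, with the same kinds of tumour cell, the difference was -0.0210 ± 0.14, against 1.07 in DMSO, which argues against this transcript as the whole difference, unless MRK-003 lowered it in the tumour cells. With the limited background the MRK-003 difference was 0.12. A rise of the osteoblasts' own Jag1 downstream of Notch is a hypothesis that was not tested further, and the dimmer Jag1 probe showed 0.06 in DMSO.

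The average MRK-003 effect was set against other splits of the 8 arrays into 4 and 4. In a plain comparison of 2 groups of 4, without the kind of tumour cell in the model, limma called 0 genes for DMSO against MRK-003, where the fit with 4 groups called 70 (2302 at an unadjusted p under 0.05). A count of 0 is reached by any split, so all 35 of 35 doing so decides nothing about chance. The highest of the others, 1454, was the split by slide, which points to a structure of the arrays. Among the 18 splits with 2 arrays of each slide on both sides, the highest other count was 1. With the limited background the real count was 13, and 2 of 35 splits called as many, the other being the split by slide with 1828. With the block and the planned background the real count was 0, which again any split reaches. With the block and the limited background together the real count was 320 and the highest of the other evenly divided splits 0, and 18 splits are too few for a share under 0.05.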
